A study of Danio rerio with 6 samples.

How the data were processed

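Testes of 6 adult zebrafish were profiled by RNA sequencing, 3 from control fish and 3 from fish exposed to polystyrene nanoplastics in the water for 96 h. Per the labels, RNA of frozen tissue was extracted with Trizol, and the sequencing company Novogene made the libraries after poly(A) enrichment. The authors deposited 1 table of raw counts, whole numbers of reads per Ensembl gene with 1 column per animal, for 32520 genes. Per the submitters' processing notes the reads were aligned with STAR to the genome build GRCz11. The version of STAR, the counting tool, the annotation release, the use of strand and the treatment of read mates are not given in the sources used here. How reads of paralogs, overlapping genes and antisense partners were shared out is therefore unknown. Columns were matched to samples by the description in each label, 0 columns were left out, and groups were taken from the titles.

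Column totals ran from 76205591 to 108273937 counts. At these depths 3 counts in a library equal between 0.0277 and 0.0394 counts per 1000000 (CPM), and floors and intervals cover counting error only. Of the counts from 10 to 99, between 66.8% and 75.1% per library were even numbers, where 50% would come by chance. Whether both mates of a pair were counted is not given in the sources used here. Where they were, counting error rests on fewer fragments than the totals state. A chi-square comparison over genes found no 2 libraries within sampling noise of each other (chi-square per degree of freedom at least 156), so all 6 were kept as separate libraries.

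Gene names came from a reference table that paired 29201 of the 32520 identifiers with a symbol, and 1.42% of counts fell on genes without one. Symbols are printed as that table gives them, many in capitals and some shared by 2 paralogs. Genes with low counts were removed with filterByExpr, which left 26108 genes. Counts were scaled by TMM and tested with edgeR 4.0.16 (glmQLFit, robust, with the default method of that version, and glmQLFTest, two-sided). Group was the only term, and p-values were adjusted by Benjamini-Hochberg at 0.05. Lists were tested with camera from limma 3.58.1 on voom values with a preset correlation of 0.01, with an estimated correlation and fry beside it, adjusted over 38 lists. Principal components used log2 CPM with a prior count of 2. The calculations ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

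The groups, tests, alternatives, 38 lists and the rule for named genes were fixed before the data were examined. The lists cover cell types of the testis and stages of germ cells, other tissues, and pathways of stress, metabolism, signalling and cell maintenance. Of 1521 listed symbols, 255 were matched through a name shared by paralogs and 107 were absent. Under the rule, with fewer than 5 genes past the threshold, the text names the 10 genes with the smallest p in each direction that have a characterised symbol and a mean of at least 1 CPM. It also names the 2 most abundant members of each list and 10 genes set in advance (STAR, CYP17A1, cyp11c1, insl3, amh, gsdf, DDX4, SYCP3, CYP1A1 and HMOX1). Genes named outside the rule are said to be.

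Alternatives were DESeq2 1.42.0 with its own size factors, limma voom, other normalizations (relative log expression, upper quartile, library totals) and other filters on low counts. Further ones were a fit that was not robust, other thresholds, the replicate number as a block, each library left out in turn, and lists without shared members. Added after seeing the data were edgeR's bias-adjusted quasi-likelihood method, halved counts, counts thinned to the smallest total, and marker lists of epidermis and kidney. The procedure was tested on simulated counts for 26108 genes, drawn gene by gene with the means and dispersions of these genes. Of those with a mean of at least 1 CPM, 200 were changed, 50 at each fold size. Shifts shared by many genes of a library were not simulated, so recovery and false calls may differ in the real libraries. For exposed against control, edgeR recovered 0 of 50 genes changed 2-fold, 13 of 50 changed 4-fold, 30 of 50 changed 8-fold and 32 of 50 changed 16-fold, with 6 calls among unchanged genes. The bias-adjusted method recovered 0, 14, 31 and 34, with 9 calls among unchanged genes. DESeq2 recovered 4, 27, 44 and 41, with 120 calls among unchanged genes.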

Results

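Testes of adult zebrafish (Danio rerio) were profiled by poly(A)-enriched RNA sequencing in 3 control fish and in 3 fish exposed to polystyrene nanoplastics, very small particles of the plastic polystyrene. The particles went into the tank water every 24 h for 96 h, and control water received none. The particle size and the dose are not given in the sources used here. Each library came from 1 animal and is named by the replicate and animal numbers of its label: control 1-2, control 2-2 and control 3-1, and exposed 2-2, exposed 3-1 and exposed 3-3. Exposed 3-1 and exposed 3-3 share a replicate number, whose meaning the labels do not give. They are treated here as independent. The deposited counts covered 32520 genes and summed to 86765952, 76205591 and 77102767 in the controls and to 108273937, 96029888 and 103874587 in the exposed libraries. Every exposed library was deeper than every control library (ratio of the mean totals 1.28). Mitochondrially encoded genes took between 4.28% and 5.74% of the counts of a library. Below, levels are TMM-scaled counts per 1000000 counts (CPM) as mean ± SD with n = 3 per group. Log2 fold changes from edgeR are exposed over control ± SE, so that positive values are higher in exposed testes. The SE is not given by edgeR. It was derived as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic.

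The comparison asked which transcripts of the testis differ after a short exposure to polystyrene nanoplastics. As whole lists, transcripts of meiosis, of the piRNA pathway, of sperm and their flagella and of the cell cycle were called lower in exposed testes, with median log2 fold changes between -0.86 and -0.69. Lists of macrophages and neutrophils, of lymphocytes, of red blood cells and of immediate early genes were called higher, with medians between 1.12 and 1.25. The lowest of these, for red blood cells, was 0.60 without exposed 2-2. Markers of the epidermis, listed after the first results, lay above 0 in 35 of 35 cases, with a median of 3.51, which was 2.099 without exposed 2-2. Markers of Sertoli cells and of spermatogonia were not called in either direction. These list calls came from camera with a preset correlation of 0.01 between genes, and none of the 24 called lists passed with an estimated correlation (smallest adjusted p = 0.317 with an estimated correlation).

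Among single genes, 0 of 26108 passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05 (smallest adjusted p = 0.0518, for cd44a). At an unadjusted p under 0.05 there were 4298 genes, 2526 higher and 1772 lower in exposed testes, where chance gives about 1305 on average. Other splits of the 6 libraries, 3 against 3, gave between 454 and 2435 such genes. At an adjusted p under 0.1 there were 17 genes, and under 0.2 there were 1731. DESeq2 called 1756 genes, 1405 higher and 351 lower, and limma voom called 0. In the simulated counts DESeq2 made 120 calls among unchanged genes, where edgeR made 6. DESeq2 called between 26 and 484 genes in the other splits of the libraries. A gene that passed in DESeq2 but not in edgeR is therefore not established as changed. EdgeR's bias-adjusted quasi-likelihood method, added after seeing the data, called 70 (65 higher and 5 lower), of which 68 were also called by DESeq2 in the same direction. The counts rested on single libraries: without exposed 3-3, edgeR called 396 genes and DESeq2 3609, and without exposed 2-2 DESeq2 called 1050. DESeq2's higher calls ranged from 711 without exposed 2-2 to 2178 without exposed 3-3. Its lower calls were 178 without control 2-2, 211 without control 1-2 and 1431 without exposed 3-3. The groups did not overlap in CPM for 6189 genes (23.7%, against 10% on average by chance with 3 against 3).

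The libraries separated by group along the first principal component of the 500 most variable genes, which held 60.7% of their variance. Exposed 3-3 scored 20.5 on that component, nearest to the controls, and exposed 2-2 scored 93.5. Spearman correlations across genes lay between 0.919 and 0.953 within controls, between 0.897 and 0.922 within exposed libraries and between 0.852 and 0.932 across the groups. Genes are not independent replicates. With 3 against 3 animals an exact permutation test of a single value cannot go below p = 0.1, so the separation was not tested.

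**Figure D1:**
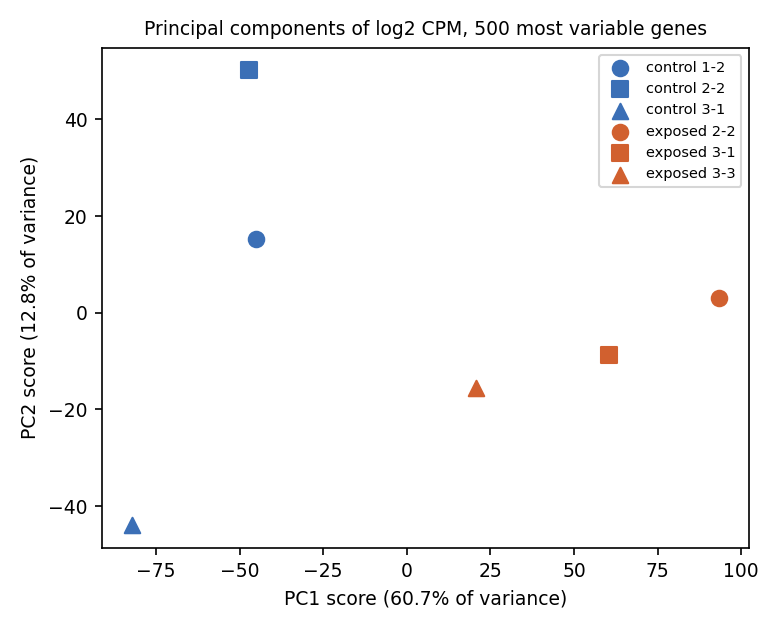
Scores of the 6 libraries on the first 2 principal components of log2 CPM (TMM-scaled, 500 most variable genes), with the percent of variance on each axis; blue symbols are control and orange symbols exposed testes. The controls lie between -82.2 and -45.0 on the first component and the exposed libraries between 20.5 and 93.5.

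The gene nearest to the threshold was cd44a (ENSDARG00000087863), which encodes a cell-surface receptor for hyaluronan, at 0.354 ± 0.141 CPM in controls and 67.2 ± 40.5 CPM in exposed testes. Its log2 fold change was 7.57 ± 0.62 (edgeR adjusted p = 0.0518, DESeq2 adjusted p = 7.93e-45). The other genes with the smallest p on the higher side also missed the threshold in edgeR (adjusted p between 0.0882 and 0.0975) and passed in DESeq2. DUSP1 (ENSDARG00000100515), a phosphatase that switches off MAP kinases, stood at 51.1 ± 11.2 CPM in controls and 306 ± 93.7 CPM in exposed testes. ARRDC2 (ENSDARG00000020761), an arrestin-domain protein, stood at 33.3 ± 1.82 CPM in controls and 135 ± 29.8 CPM in exposed testes. Genes used by blood cells were among them. The haematopoietic cytoskeletal adaptor hcls1 (ENSDARG00000012729) had 14.6 ± 1.04 CPM in controls and 61.2 ± 12.6 CPM in exposed testes. INPP5D (ENSDARG00000074283), the lipid phosphatase SHIP1 of haematopoietic cells, had 6.58 ± 1.297 CPM in controls and 30.3 ± 3.45 CPM in exposed testes. The transcobalamin gene tcnbb (ENSDARG00000091996) had a log2 fold change of 3.87 ± 0.46, and c1ql1 (ENSDARG00000043436) one of 1.79 ± 0.22. COL10A1 (ENSDARG00000054753), collagen X, had 0 counts in all 3 controls and 19.4 ± 13.8 CPM in exposed testes, at least 509-fold higher than the floor of 3 counts per control library. Likewise smim24 (ENSDARG00000095633) had 0 control counts and 5.81 ± 2.16 CPM in exposed testes, at least 153-fold higher. For arid6 (ENSDARG00000069988), with 3 counts over the 3 controls and 6577 over the 3 exposed libraries, the ratio was 1685 (95% exact binomial interval 576 to 8171, counting error only).

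On the lower side, none of the 10 genes with the smallest p passed in edgeR (adjusted p between 0.106 and 0.139), and all 10 passed in DESeq2. Several act in meiotic recombination or the cell cycle. MEIOB (ENSDARG00000062442), a DNA-binding protein of meiotic recombination, stood at 144 ± 43.2 CPM in controls and 52.8 ± 5.42 CPM in exposed testes. The gene rnf212b (ENSDARG00000093723), of the family that designates crossovers, stood at 77.9 ± 22.0 CPM in controls and 25.8 ± 5.17 CPM in exposed testes. RAD54L (ENSDARG00000018623), a motor of homologous recombination, had a log2 fold change of -1.23 ± 0.20, and CDK2 (ENSDARG00000026577), a cyclin-dependent kinase, one of -1.32 ± 0.24. NEK10 (ENSDARG00000025335), a kinase of ciliated cells, had -1.84 ± 0.26, dzip1l (ENSDARG00000074265), a protein of the base of the cilium, -1.47 ± 0.25, and morn2 (ENSDARG00000071360) -1.16 ± 0.21. The remaining 3 were CAMKV (ENSDARG00000005141) at -1.51 ± 0.23, dhrs12la (ENSDARG00000010764) at -3.42 ± 0.54 and THSD7A (ENSDARG00000090496) at -2.24 ± 0.38.

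**Figure D2:**
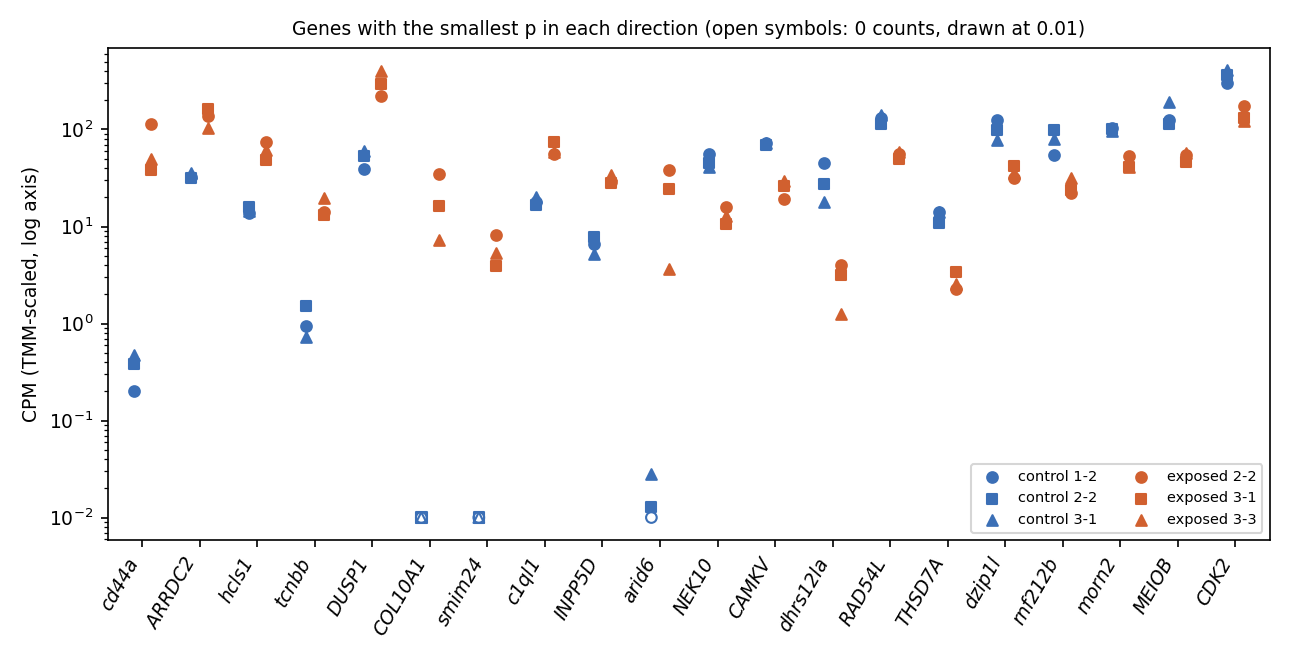
TMM-scaled CPM (log axis) of each library for the 10 genes with the smallest edgeR p on the higher side and the 10 on the lower side; blue symbols are controls, orange symbols exposed testes, and open symbols mark 0 counts. In all 20 genes the 3 exposed libraries lie on one side of the 3 controls, which a choice by smallest p favours. The groups did not overlap in 23.7% of all genes tested. No gene passed the adjusted threshold in edgeR.

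Camera called the lists of meiosis, of the piRNA pathway and of sperm lower in exposed testes (adjusted p = 2.27e-16, 9.19e-09 and 1.17e-10), with adjusted p = 0.317, 0.339 and 0.415 with an estimated correlation. No member of the 38 lists passed over all 26108 genes in edgeR, so the counts of members that passed are those adjusted over the list alone. Counts of members above or below 0 stand beside 13599 above and 12509 below 0 among all genes. In the meiosis list, 29 of 30 members had a log2 fold change below 0 and 24 were lower when adjusted over the list alone, against 0 over all genes and 14 by DESeq2. Its most abundant members were SYCP1, a backbone protein of the synaptonemal complex, at 1831 ± 137 CPM in controls and 1052 ± 284 CPM in exposed testes, and HORMAD1, of the meiotic chromosome axis, at 862 ± 213 CPM in controls and 425 ± 84.9 CPM in exposed testes. SYCP3, of the same axis, had a log2 fold change of -1.18 ± 0.36. In the piRNA list, which holds the pathway that silences transposons in germ cells, 16 of 18 members were below 0 and 10 passed adjusted over the list alone. PIWIL1 had a log2 fold change of -0.74 ± 0.26 and TDRD6 one of -0.76 ± 0.21. Among spermatid and sperm genes, 26 of 27 were below 0 and 5 passed adjusted over the list alone. ROPN1L, a flagellar protein, stood at 517 ± 86.0 CPM in controls and 229 ± 45.9 CPM in exposed testes, and the sperm glycolytic enzyme GAPDHS at -0.46 ± 0.20 on the log2 scale.

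All 42 measured genes of axonemal dyneins and cilium assembly had log2 fold changes below 0 (median -0.71; all below 0 also under 3 other scalings). The 3 other scalings differed little, with medians over all genes between 0.01 and 0.06, so they are a weak check of direction. Of the 42 genes, 0 passed adjusted over the list alone, 18 had an unadjusted edgeR p under 0.05 and 4 were called by DESeq2. The dynein heavy chains DNAH1 and DNAH6 had -0.79 ± 0.32 and -0.81 ± 0.37. The same held for all 57 genes of the cell cycle and replication list (median -0.72; all below 0 also under 3 other scalings), of which 1 passed adjusted over the list alone and 33 had an unadjusted p under 0.05. TOP2A, a topoisomerase of dividing cells, stood at 529.6 ± 64.4 CPM in controls and 294 ± 92.8 CPM in exposed testes. The replication clamp PCNA stood at 465 ± 101 CPM in controls and 294 ± 81.9 CPM in exposed testes. Of the DNA repair genes 69 of 76 were below 0, with RPA1 at -0.55 ± 0.30 and the mismatch repair gene MSH6 at -0.57 ± 0.29. Of the proteasome genes 44 of 46 were below 0, with PSMC5 at -0.66 ± 0.21 and PSMA5 at -0.55 ± 0.21. Adjusted over the list alone, 2 DNA repair genes and 1 proteasome gene passed. These 4 lists were called lower by camera (adjusted p = 9.94e-15, 9.48e-21, 3.96e-13 and 2.79e-14), with adjusted p = 0.537, 0.339, 0.374 and 0.339 with an estimated correlation.

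Markers of spermatogonia, the germline stem and early progenitor cells, went both ways (13 of 19 above 0) and the list was not called (camera adjusted p = 0.517). Its most abundant member, PIWIL1, stood at 1207 ± 176 CPM in controls and 721 ± 211 CPM in exposed testes. DDX4 (vasa), an RNA helicase of germ cells, had 554 ± 26.4 CPM in controls and 359 ± 141 CPM in exposed testes (log2 fold change -0.62 ± 0.29). DAZL and epcam were named after their values were seen. DAZL had a log2 fold change of -0.96 ± 0.24. The list also holds epcam, an epithelial adhesion gene, at 4.90 ± 1.07, with 1260.3, 309 and 91.5 CPM in exposed 2-2, 3-1 and 3-3. The missing call therefore does not show that transcripts of early germ cells were unchanged.

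Camera called the list of Leydig cells and steroid synthesis lower in exposed testes (adjusted p = 0.00522), with adjusted p = 0.537 with an estimated correlation. In it 16 of 19 members were below 0 (median -0.69), and 0 passed adjusted over the list alone and 0 over all genes. At an unadjusted edgeR p under 0.05, 5 were lower and 1 higher, and DESeq2 called 0 lower and 1 higher. STAR, which brings cholesterol into mitochondria, stood at 1146 ± 286 CPM in controls and 703 ± 186 CPM in exposed testes (log2 fold change -0.70 ± 0.29). CYP17A1 had -0.90 ± 0.54, cyp11c1, the enzyme on the way to 11-ketotestosterone, -0.83 ± 0.34, and the Leydig cell hormone insl3 -0.89 ± 0.53. Without control 2-2, the highest control for CYP17A1 (1228 CPM against 301 and 469 CPM), its log2 fold change was -0.12. The list's sulfotransferase gene sult2st3, named after its values were seen, went the other way, at 9.26 ± 4.32 CPM in controls and 113 ± 77.5 CPM in exposed testes. The call ended without exposed 3-3 (adjusted p = 0.176) and without control 2-2 (adjusted p = 0.102, median -0.42). The Sertoli cell list was not called (camera adjusted p = 0.369; 9 of 18 below 0). Its member gsdf stood at 1111 ± 117 CPM in controls and 648 ± 255 CPM in exposed testes, and amh, anti-Müllerian hormone, at 573 ± 45.8 CPM in controls and 409 ± 61.6 CPM in exposed testes. ALDH1A2, which makes retinoic acid, stood at 599 ± 149 CPM in controls and 567 ± 124 CPM in exposed testes. The list of sex steroid and gonadotropin receptors was called higher by camera (adjusted p = 0.0498, median 0.36, 22 of 29 above 0), with adjusted p = 0.537 with an estimated correlation. The list also holds receptors for thyroid hormone, retinoids, corticosteroids and anti-Müllerian hormone. Its call is therefore not one of sex steroid and gonadotropin receptors alone. PGRMC1 had 0.08 ± 0.25 and the glucocorticoid receptor NR3C1 0.64 ± 0.26. That call ended without control 1-2 (adjusted p = 0.0541), control 3-1 (0.114), exposed 2-2 (0.0856, median 0.55) or exposed 3-1 (0.373).

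Camera called the lists of macrophages and neutrophils, of T, B and NK cells and of red blood cells higher in exposed testes (adjusted p = 1.97e-09, 3.12e-05 and 0.00124), with adjusted p = 0.317, 0.339 and 0.481 with an estimated correlation. Of the macrophage and neutrophil genes 33 of 43 were above 0, 16 were higher adjusted over the list alone, against 0 over all genes, and 18 were called by DESeq2. The antigen-presentation chaperones cd74a and cd74b were among the abundant ones. The former had 583 ± 166 CPM in controls and 1843 ± 792 CPM in exposed testes, and the latter 320.2 ± 65.7 CPM in controls and 1255 ± 706 CPM in exposed testes. Of the genes of T, B and NK cells 22 of 28 were above 0 and 3 passed adjusted over the list alone. The immunoglobulin heavy chain ighm had 1.16 ± 0.67, whereas the recombinase gene RAG2 had -0.74 ± 0.32. Of the red blood cell genes 14 of 19 were above 0 and 6 passed adjusted over the list alone. The adult alpha globin hbaa1 stood at 1076 ± 650.1 CPM in controls and 3207 ± 732 CPM in exposed testes and the carbonic anhydrase cahz at 124 ± 35.8 CPM in controls and 269 ± 115 CPM in exposed testes. The interferon list (34 of 50 above 0, median 0.47) and the inflammation list (39 of 68 above 0) were also called higher (adjusted p = 0.00532 and 0.00356), with adjusted p = 0.537 and 0.537 with an estimated correlation. Adjusted over the list alone, 0 interferon genes were higher and 12 had an unadjusted edgeR p under 0.05. DESeq2 called 3, near its share over all genes (1405 of 26288 higher). For inflammation 0 were higher adjusted over the list alone, 15 were higher and 1 lower at an unadjusted edgeR p under 0.05, and DESeq2 called 7 higher. The class I light chain gene b2m stood at 1458 ± 283 CPM in controls and 2625 ± 809 CPM in exposed testes, and b2ml had a log2 fold change of 1.12 ± 0.39. NOS2, inducible nitric oxide synthase, had 3.30 ± 2.35 CPM in controls and 1095 ± 1128 CPM in exposed testes (edgeR adjusted p = 0.170). In exposed 2-2, 3-1 and 3-3 it had 2285, 957 and 42.2 CPM. The most abundant member of the inflammation list, complement c3a.1, had a log2 fold change of -2.53 ± 2.07, with 5412 CPM in control 3-1. The interferon call ended without control 1-2 (adjusted p = 0.0548, median 0.28), control 2-2 (0.115) or exposed 2-2 (0.154, median 0.20), and the inflammation call without control 2-2 (0.437). The inflammation median of 0.22 went below 0 without control 2-2 (-0.03) and without exposed 2-2 (-0.03), the list staying called in the latter case (adjusted p = 0.0207). It was 0.04 without control 1-2, 0.35 without exposed 3-3 and 1.19 without control 3-1 (adjusted p = 1.20e-09), without which the interferon median was 0.90.

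Immediate early genes, which cells switch on within minutes of a stimulus, formed the list with the most members higher adjusted over the list alone, among the 38 lists. In it 46 of 53 were above 0, 22 were higher adjusted over the list alone, against 0 over all genes, and 24 were called by DESeq2. BTG1, which restrains proliferation, stood at 242 ± 17.00 CPM in controls and 463 ± 133 CPM in exposed testes. CEBPB had 24.5 and 31.6 CPM in 2 controls but 283 CPM in control 3-1 (log2 fold change 1.77 ± 1.06). Circadian clock genes had a median log2 fold change of 0.48 (36 of 43 above 0), and of 0.32 without exposed 2-2. Against the control means their median log2 ratio was 0.72, 0.51 and 0.08 in exposed 2-2, 3-1 and 3-3. Adjusted over the list alone 0 of them were higher, 14 had an unadjusted edgeR p under 0.05 and 5 were called by DESeq2. The clock output gene tefa had a log2 fold change of 0.91 ± 0.35 and the kinase csnk1da one of 0.01 ± 0.29. Camera called both lists higher (adjusted p = 1.96e-13 and 4.42e-05), with adjusted p = 0.317 and 0.537 with an estimated correlation. The times of dissection are not given in the sources used here.

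Among response pathways, genes of xenobiotic metabolism (52 of 76 above 0, median 0.42), of lysosome, endocytosis and autophagy (56 of 93, median 0.24) and of p53 and apoptosis (33 of 53, median 0.15) were called higher by camera (adjusted p = 0.00283, 0.0125 and 0.0275), with adjusted p = 0.537, 0.537 and 0.537 with an estimated correlation. Adjusted over the list alone, 0, 0 and 6 of their members were higher and 0, 0 and 1 lower. At an unadjusted edgeR p under 0.05, 8, 15 and 13 were higher and 2, 5 and 3 lower. DESeq2 called 4, 8 and 7 higher and 0, 0 and 2 lower. Over all 26108 genes, 13599 were above 0, and 2526 were higher and 1772 lower at that unadjusted p. DESeq2 called 1405 of 26288 genes higher. The 8 and 4 xenobiotic genes counted as higher were near these shares, so they say little about that list. The abundant xenobiotic genes EPHX1 and cyp2p10 had -0.39 ± 0.39 and -0.10 ± 0.41. CYP1A1, the target of the aryl hydrocarbon receptor, stood at 29.6 ± 41.4 CPM in controls and 53.9 ± 31.7 CPM in exposed testes. The lysosomal gene PSAP had 0.47 ± 0.20 and gabarapb -0.06 ± 0.23. Of the p53 list, CCNG1 had 0.27 ± 0.25 and bida, a pro-apoptotic gene, -0.79 ± 0.21. The xenobiotic median was 0.18 without exposed 3-1 and 0.77 without control 3-1, and 0.22 and 0.27 without control 2-2 and exposed 2-2. The lysosome call ended without exposed 2-2 (adjusted p = 0.430, median 0.11) or control 2-2 (0.0623), and the p53 call without control 1-2 (0.0732), control 2-2 (0.164) or exposed 2-2 (0.119). The p53 median was 0.36 without control 3-1 and 0.30 without exposed 3-3. Antioxidant and glutathione genes were not called (30 of 56 above 0, camera adjusted p = 0.230), with the ferritin gene fth1a at 0.57 ± 0.27, the haem oxygenase HMOX1 at 0.49 ± 0.25 and the thioredoxin inhibitor TXNIP at 408 ± 57.0 CPM in controls and 1120.5 ± 173 CPM in exposed testes. Heat shock genes (31 of 49 below 0; HSP90AB1 0.06 ± 0.22, HSPA8 0.36 ± 0.27) and genes of endoplasmic reticulum stress (19 of 36 below 0; HSPA5 -0.94 ± 0.42, atf4a 0.32 ± 0.24) were not called either (camera adjusted p = 0.112 and 0.694).

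Transcripts of other tissues differed between libraries. Cell junction genes (39 of 51 above 0, 6 higher and 1 lower adjusted over the list alone) and genes of fibroblasts and extracellular matrix (33 of 39 above 0) were called higher by camera (adjusted p = 0.00514 and 5.30e-04), with adjusted p = 0.537 and 0.537 with an estimated correlation. Of the matrix genes 0 were higher adjusted over the list alone, and 7 were higher and 1 lower at an unadjusted edgeR p under 0.05. DESeq2 called 2 higher, near its share over all genes (1405 of 26288). CLDN11 had 0.48 ± 0.33, ctnnb2 -0.21 ± 0.20, FN1 0.11 ± 0.60 and COL1A1 0.01 ± 0.22. Without control 1-2 the extracellular matrix call ended (adjusted p = 0.0558). Beside these groups stood the keratins of the epidermis, looked at after the first results. Of these, krt5 had 24.5 ± 5.17 CPM in controls and 2449.6 ± 1968 CPM in exposed testes, with 3672, 3498 and 179 CPM in exposed 2-2, 3-1 and 3-3. All 35 measured markers of an epidermis list were above 0, also under 3 other scalings, with a median log2 fold change of 3.51. Without exposed 2-2 the median was 2.099, and 34 of 35 were above 0 without exposed 2-2, exposed 3-1 or control 1-2. The oocyte and follicle list was called higher (camera adjusted p = 0.00809; 21 of 29 above 0, 6 higher and 1 lower adjusted over the list alone), with adjusted p = 0.537 with an estimated correlation. The call ended without exposed 3-3 (adjusted p = 0.0831). Its abundant member org had a log2 fold change of -0.75 ± 0.23, and the zona pellucida gene zp3d.2 stood at 62.2 ± 31.9 CPM in controls and 31.0 ± 8.05 CPM in exposed testes. In contrast, zp3a.1, named after its values were seen, had 0.0659 ± 0.0786 CPM in controls and 10.96 ± 6.68 CPM in exposed testes. Pancreas and intestine genes were called higher (camera adjusted p = 0.00273; 31 of 38 above 0, median 0.72, 4 passed adjusted over the list alone), with adjusted p = 0.537 with an estimated correlation. The trypsin genes prss59.1 and prss1 were highest in exposed 3-1, at 510.4 and 619 CPM, and the call ended without exposed 3-1 (adjusted p = 0.266, median -0.17) or control 3-1 (0.228, median 0.27). Without control 1-2 the median was 1.28. Liver genes were not called (camera adjusted p = 0.175) and varied between libraries in both groups. Against the control means their median log2 ratio was 2.98 in control 3-1, -2.61 in control 2-2 and 1.84 in exposed 3-1. The transferrin gene tfa had 8831 CPM in control 3-1, 187 and 61.7 CPM in the other controls and between 226 and 1708 CPM in exposed testes. Complement c3a.1 had 5412 CPM in control 3-1. Without control 3-1 the liver list was called higher (camera adjusted p = 8.62e-07, median log2 fold change 1.95), as it was without exposed 2-2 (adjusted p = 0.00641, median 0.07). Without exposed 3-1 its median was -1.35.

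**Figure D3:**
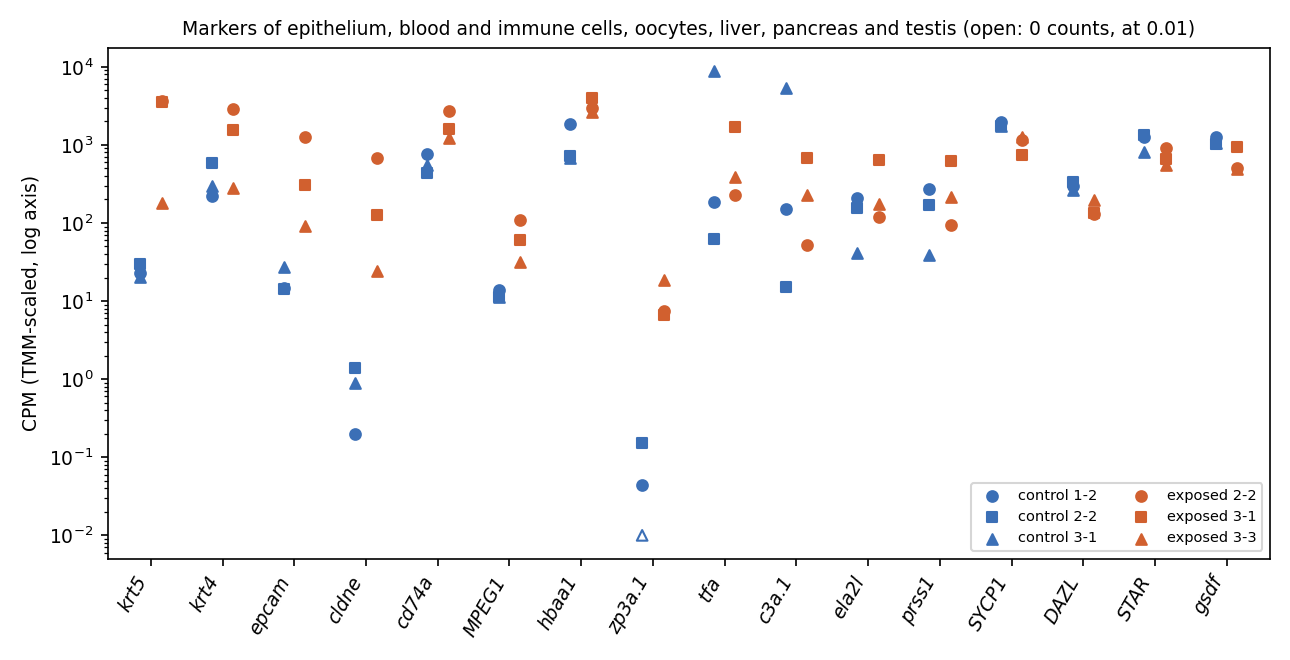
TMM-scaled CPM (log axis) of each library for markers of epithelium (krt5, krt4, epcam, cldne), immune and blood cells (cd74a, MPEG1, hbaa1), oocytes (zp3a.1), liver (tfa, c3a.1), pancreas (ela2l, prss1) and testis (SYCP1, DAZL, STAR, gsdf), chosen after their values were seen; blue symbols are controls, orange symbols exposed testes, and open symbols mark 0 counts. For krt5 the controls lie between 20.1 and 30.2 CPM and the exposed libraries between 179 and 3672 CPM.

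The lists of oxidative phosphorylation, mitochondrially encoded proteins, glycolysis, cholesterol, cytosolic ribosomal proteins and chromatin had medians between -0.36 and 0.18. Nuclear genes of oxidative phosphorylation were called lower by camera (81 of 94 below 0, median -0.36, adjusted p = 5.27e-08), with adjusted p = 0.537 with an estimated correlation. Without control 3-1 the median was -0.18 (adjusted p = 0.00410). Adjusted over the list alone 0 of them were lower. At an unadjusted edgeR p under 0.05, 17 were lower and 1 higher, and 0 were called by DESeq2. The ATP synthase genes atp5mc3b and ATP5F1B had -0.35 ± 0.30 and -0.32 ± 0.23. Mitochondrially encoded genes were not called (camera adjusted p = 0.146; 10 of 13 below 0), with MT-CO1 at 0.11 ± 0.22 and MT-CO2 at -0.01 ± 0.20. Neither were glycolysis (GAPDH -0.35 ± 1.11, LDHB 0.18 ± 0.28), cholesterol synthesis and uptake (TM7SF2 -0.70 ± 0.32, NPC2 0.17 ± 0.23), cytosolic ribosomal proteins (RPS2 0.05 ± 0.26, RPLP0 -0.06 ± 0.25) and DNA methylation and chromatin (KDM1A -0.53 ± 0.25, kdm5c -0.46 ± 0.24), with camera adjusted p = 0.707, 0.270, 0.288 and 0.495. Markers of smooth and skeletal muscle (acta2 0.09 ± 0.32, TAGLN 0.11 ± 0.36), endothelium (plvapb 0.95 ± 0.39, stab1 0.04 ± 0.25) and adipocytes (FASN -0.33 ± 0.23, LPL 0.89 ± 0.68) were not called (camera adjusted p = 0.0518, 0.0743 and 0.888), although 26 of 32 muscle and 18 of 23 endothelial genes were above 0. The list's median, mean and test differed in sign for liver (median -0.45, test higher), endoplasmic reticulum stress (median -0.03, test higher), adipocytes (median -0.18, mean 0.13, test higher), Sertoli cells (median -0.03, mean 0.16, test lower) and chromatin (median -0.05, mean 0.02, test lower).

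**Figure D4:**
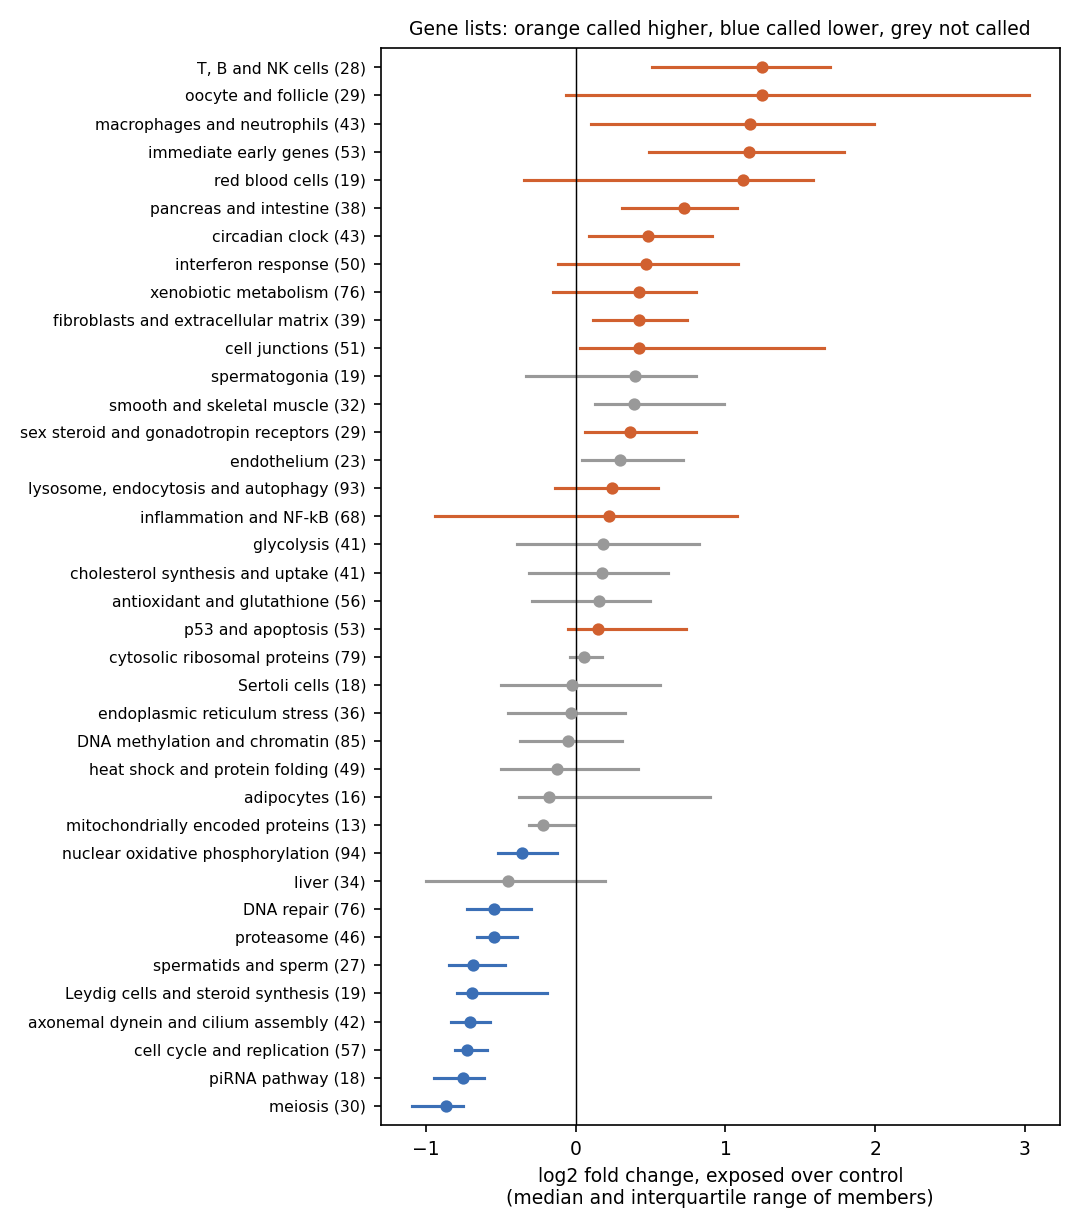
Median log2 fold change, exposed over control (points), and interquartile range of the members (lines) for the 38 gene lists, with the number of genes tested in brackets; orange lists were called higher and blue lists lower by camera with the preset correlation, and grey lists were not called. The medians run from -0.86 for meiosis to 1.25 for T, B and NK cells, and no call passed with an estimated correlation.

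Fry, which asks whether a list's genes move one way on balance, called 0 of 38 lists (smallest adjusted p = 0.0922), where camera with the preset correlation called 24, and fry's test for change in either direction called 16. In counts simulated gene by gene with the dispersions of these genes, edgeR recovered 0 of 50 genes changed 2-fold, 13 of 50 changed 4-fold and 30 of 50 changed 8-fold. DESeq2 recovered 4, 27 and 44 of them, but made 120 calls among unchanged genes, against 6 by edgeR. Shifts shared by many genes of a library were not simulated.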

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

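Chosen only after seeing the data were edgeR's bias-adjusted method, halved counts, thinned counts and marker lists without single libraries. Against 0 genes in edgeR (4298 at an unadjusted p under 0.05), DESeq2 called 1756 (1405 higher, 351 lower) and the bias-adjusted method 70 (65 higher, 5 lower). With no filter edgeR called 12 genes, 12 of them higher. Relative log expression, upper quartile, library totals, halved counts and thinned counts each gave 1 gene, which was higher. Limma voom, the filter at 1 CPM, the fit that was not robust and both other thresholds gave 0. Leaving out 1 library gave 0 to 396 genes, 0 to 370 higher and 0 to 26 lower. The 396 came without exposed 3-3. Without exposed 2-2 it was 1, and without each of the other 4 libraries 0. DESeq2 gave 1050 genes without exposed 2-2 and 3609 without exposed 3-3. The cause was not tested.

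Camera with the preset correlation called 24 lists, 19 to 27 with 1 library left out, and 0 with an estimated correlation. Of these, 14 passed under each other normalization and filter, with halved or thinned counts, with the replicate block and without each library. They are the lists of meiosis, sperm, cilium, piRNA, DNA repair, cell cycle, proteasome, oxidative phosphorylation, macrophages, lymphocytes, red blood cells, immediate early genes, circadian clock and cell junctions. The cell junction list shares 4 members with the epidermis markers. The other 10 had adjusted p over the alternatives with the preset correlation of sex steroid and gonadotropin receptors 0.0125 to 0.373, p53 and apoptosis 0.00125 to 0.164, interferon response 1.22e-05 to 0.154, Leydig cells and steroid synthesis 2.48e-04 to 0.176 and oocyte and follicle 6.86e-04 to 0.118. For the rest these were inflammation and NF-kB 1.20e-09 to 0.921, lysosome, endocytosis and autophagy 0.00281 to 0.430, pancreas and intestine 4.64e-06 to 0.266, xenobiotic metabolism 7.17e-05 to 0.337 and fibroblasts and extracellular matrix 1.32e-05 to 0.0558. The receptor call also ended with upper quartile (0.0666) and with no filter (0.0681), and the p53 call with members of 1 list only (0.0518). Muscle was called with the filter at 1 CPM (0.0306) and with thinned counts (0.0479). Lists that gained a call without control 3-1 were liver (8.62e-07), cytosolic ribosomal proteins (0.00119), antioxidant and glutathione (0.00416), endoplasmic reticulum stress (0.00735) and endothelium (0.00634), with adjusted p in brackets. Without control 1-2 they were smooth and skeletal muscle (0.0245) and mitochondrially encoded proteins (0.0245), and without exposed 2-2 liver (0.00641), endothelium (0.0314), smooth and skeletal muscle (0.0485) and mitochondrially encoded proteins (0.0129). Without exposed 3-1 they were smooth and skeletal muscle (0.0206), mitochondrially encoded proteins (0.00572) and cytosolic ribosomal proteins (0.0293), the last in the opposite direction, and without exposed 3-3 cholesterol synthesis and uptake (0.0322). The first component held 45.8% of the variance with 2000 genes and 58.7% with variance stabilised values.

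The labels do not say what their replicate numbers stand for. Deviations of same-numbered libraries correlated across genes at -0.00632, 0.0194 and -0.0344, and those of other pairs between -0.0261 and 0.0383. The numbers were therefore not taken to pair animals. Deviations from a mean of 3 libraries tend to oppose each other within a group, so this check cannot exclude a shared origin. With the replicate block 5 genes were called (3 higher, 2 lower) and 20 lists. The lists of oocytes, inflammation, xenobiotic metabolism, p53 and sex steroid receptors lost their call and muscle gained one. With the replicate block, camera's test turned direction for lists it had not called, whose medians did not all change sign. They were liver -0.34, adipocytes -0.0469, endoplasmic reticulum stress -0.0902, glycolysis 0.0373, DNA methylation and chromatin 0.10 and cytosolic ribosomal proteins -0.0432. For genes that edgeR had not called, the log2 fold changes that turned were ALDH1A2 0.0718, stab1 -0.0473, FN1 -0.36, COL1A1 -0.0122 and PGRMC1 -0.0321.

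With limma voom the log2 fold changes that turned were TAGLN -0.0153, FN1 -0.0168, COL1A1 -0.00893, tfa 0.19, GAPDH 0.34 and csnk1da -0.0313, with upper quartile COL1A1 -0.0301 and csnk1da -0.0479, and with library totals MT-CO2 0.00673. With no filter they were COL1A1 -0.00925 and csnk1da -0.00670, and camera's test of adipocytes turned, with a median of -0.23, below 0 as before. With halved counts they were COL1A1 -0.00479 and csnk1da -0.00246. Leaving out 1 library turned 22 genes, whose log2 fold changes ranged as ALDH1A2 -0.23 to 0.14, stab1 -0.12 to 0.25, FN1 -0.74 to 0.51, COL1A1 -0.10 to 0.15, PGRMC1 -0.12 to 0.22 and cyp2p10 -0.44 to 0.11. Further ranges were csnk1da -0.32 to 0.18, tfa -3.32 to 2.62, c3a.1 -3.74 to 1.93, MT-CO2 -0.16 to 0.0799, GAPDH -1.17 to 1.59 and gabarapb -0.18 to 0.0707. Likewise there were RPLP0 -0.23 to 0.0904, acta2 -0.28 to 0.33, TAGLN -0.34 to 0.41, prss59.1 -0.22 to 1.13, prss1 -0.0566 to 1.56 and LPL -0.0553 to 1.41, as well as HSP90AB1 -0.0886 to 0.21, MT-CO1 -0.0232 to 0.26, LDHB -0.12 to 0.34 and RPS2 -0.24 to 0.24. It also turned the test of 8 lists, whose medians ranged as endoplasmic reticulum stress -0.17 to 0.26, glycolysis 0.0156 to 0.28, DNA methylation and chromatin -0.17 to 0.0411, cytosolic ribosomal proteins -0.10 to 0.15, liver -1.35 to 1.95, cholesterol synthesis and uptake 0.0672 to 0.29, adipocytes -0.21 to 0.0112 and mitochondrially encoded proteins -0.45 to 0.0799. The cause was not tested. Depth limits genes without counts, since 3 counts in a library equal 0.0277 to 0.0394 CPM.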

Other observations

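The contrasts between cell types, the test of ovarian RNA, the thinned counts, the counts over other splits and the values here without single libraries were chosen only after the results they bear on were seen. So were the genes named here outside the rule. Beside the lists, 81 genes lay under 0.3 CPM in all 3 controls and above 1 CPM in all 3 exposed libraries, against 3 genes the other way round. With 1 library fewer to meet these limits there were 153, 142 and 129 without control 1-2, 2-2 and 3-1 (7, 11 and 5 the other way round). Without exposed 2-2, 3-1 and 3-3 there were 106, 107 and 173 (11, 11 and 19). The 81 genes included the claudins cldn8.2 and cldnf, which seal epithelia, at 39.6 ± 44.5 and 24.7 ± 31.0 CPM in exposed testes. The epithelial transcription factor genes znf750 and SP6 stood at 11.9 ± 11.9 and 4.12 ± 3.45 CPM there, and the intestinal bile acid binding gene FABP6 at 12.9 ± 10.2 CPM. Others were the class I gene mhc1uma (3.01 ± 1.59 CPM), ms4a17a.12 (11.03 ± 12.2 CPM) and the cytokine gene il19l (5.51 ± 4.78 CPM). Exposed 2-2 was the highest library for 50 of the genes, exposed 3-1 for 14 and exposed 3-3 for 17.

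Among genes of immune cells, MPEG1 (ENSDARG00000055290), a pore-forming protein of macrophages, stood at 12.1 ± 1.62 CPM in controls and 67.3 ± 39.1 CPM in exposed testes. The T cell kinase gene lck stood at 5.72 ± 0.948 CPM in controls and 13.8 ± 1.76 CPM in exposed testes. The immediate early transcription factor genes egr1 and FOSB stood at 29.2 ± 7.62 CPM in controls and 235 ± 168 CPM in exposed testes, and at 7.49 ± 4.17 CPM in controls and 92.2 ± 74.8 CPM in exposed testes, respectively. In exposed 3-3 alone they had 60.9 and 11.8 CPM. The transcription factor gene CEBPA stood at 31.4 ± 7.38 CPM in controls and 97.7 ± 4.12 CPM in exposed testes. None of these 5 passed over all genes in edgeR (adjusted p = 0.139, 0.167, 0.157, 0.195 and 0.106), and all 5 passed in DESeq2.

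Of the genes near absent in controls, skin carried along at dissection may account for a part. The 35 epidermis markers, listed after the first results but before their values were looked at as a list, had a median log2 fold change of 3.51 (95% bootstrap interval 2.08 to 4.28). The median was 2.099 (1.37 to 2.71) without exposed 2-2. Bootstrap intervals here and below resample genes and do not cover the spread between animals. Of the markers 29 were at 1 CPM or more in controls, and 4 were in another list, whose values had already been computed. Above their control mean lay 35, 34 and 25 of them in exposed 2-2, 3-1 and 3-3, among them krt5 with 24.5 ± 5.17 CPM in controls and 2449.6 ± 1968 CPM in exposed testes, while the abundant krt91 and krt15, at 1066 ± 655 and 768 ± 413 CPM in controls, had 748 and 412 CPM in exposed 3-3. Against greater depth as the cause, 78 such genes were counted after thinning to the smallest total, while kidney tissue and an effect of exposure itself, which was not tested, stay open. The 21 kidney markers (19 at 1 CPM or more in controls, 1 in another list) had a median of 1.03 (0.19 to 1.39) but 0.08 (-0.10 to 0.66) without exposed 2-2 and 0.67 without control 3-1, and 16, 9 and 14 of them lay above their control mean in exposed 2-2, 3-1 and 3-3.

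A lower share of germ cells alone would raise the markers of all other cell types alike. The library medians of the macrophage list and of the Leydig and Sertoli lists moved apart by 1.41 on the log2 scale (0.54 to 2.29, 2 SE, n = 3 per group). Without control 1-2 the interval reached below 0 (-0.06 to 2.86). These lists were contrasted after their calls were seen, and 2 SE is a narrow bound with n = 3 per group. The contrast therefore cannot decide whether a lower share of germ cells is the whole cause. RNA of other cells or tissue could dilute all testis cells alike, and the change of germ cell medians minus that of Leydig and Sertoli medians was -0.55 (-1.15 to 0.05), an interval too wide to decide that lay below 0 without control 2-2 (-1.02 to -0.05) or exposed 3-3 (-1.30 to -0.31). An immune response or a loss of germ cell transcripts through exposure also stays open, as untested.

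For the zona pellucida genes, a small share of ovarian RNA in the exposed libraries stays open, as no value decides it. Of the 18 members of the oocyte and follicle list under 2 CPM in controls 16 were higher in exposed testes, but 9 of the 16 are the zona pellucida genes themselves, and a choice by low control levels favours higher values. Of the 11 members at or above 2 CPM, where a high baseline would hide a small share, 5 were higher. Reads shared between paralogs could raise the family together, and the 9 low members outside it, chosen by the same control level, had a median log2 fold change of 1.51 (95% bootstrap interval -0.15 to 3.07), with the oocyte linker histone gene h1m at 0.290 ± 0.270 CPM in controls and 7.65 ± 3.41 CPM in exposed testes, which leaves this open. Expression of oocyte genes in the testis through exposure stays open, as untested.

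The 6 libraries can be split 3 against 3 in 10 ways, which cannot give a share under 0.05. The real split gave 4298 genes at an unadjusted edgeR p under 0.05 and the highest other split 2435 (1 of 10 splits reached the real count). For DESeq2 these were 1756 and 484 (1 of 10), and for edgeR's bias-adjusted method 70 and 1 (1 of 10). For edgeR's default method they were 0 and 1, so that 10 of 10 splits reached the real count. For lists called by camera they were 24 and 26 (2 of 10). The split that exchanges control 3-1 and exposed 3-3 was the highest other one in each of these counts.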
